A study of Mus musculus with 2 samples.

How the data were processed

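The series holds 2 10x Chromium libraries of iChip-enriched whole blood from wild-type mice after burn/tenotomy, in 1 group. Each library came as a matrix of genes by barcodes. The values are raw UMI counts per gene and barcode as deposited: whole numbers that were not normalized. Per the submitters' processing notes, Cell Ranger 7.1.0, Seurat 5 and the mm10 build were named, with no role given for Seurat. How barcodes were called and whether doublets had been removed is not given in the sources used here. The lowest UMI number of a barcode was 500 in replicate 1 and 501 in replicate 2. No barcode sequence was shared by the libraries (0). Of 32285 gene IDs, 32235 (99.8%) were matched to GENCODE M21, which uses the mm10 assembly, and gene coordinates were taken from it. A symbol given to more than 1 gene (40 symbols) was not used for a list.

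Barcodes with at least 100 detected genes and at most 20% mitochondrial UMIs were kept. Depth after this filter was 3142209 UMIs in replicate 1 and 2519848 in replicate 2. Kept barcodes were scaled to 10000 UMIs, log-transformed and clustered over both libraries without integration in scanpy 1.11.5 (2000 variable genes found in at least 3 barcodes, 20 principal components, 15 neighbours, Leiden resolution 0.5 with igraph 0.11.9). All function-list genes were left out of the clustering. Doublets were called per library with Scrublet (expected rate 0.05) and kept, since its calls took most of 1 library and almost nothing of the other.

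Clusters were named from 18 marker lists fixed before the data were examined. They cover neutrophils, monocytes or macrophages, dendritic cells, B cells, plasma cells, T cells, NK cells, basophils or mast cells, eosinophils, platelets or megakaryocytes, erythroid cells, haematopoietic progenitors, endothelial, mesenchymal, pericyte or smooth muscle, skeletal muscle, epithelial or keratinocyte, and Schwann cells. The naming rule was set after seeing the data. A cluster with over 50% erythroid UMIs was erythroid-like. Any other took the list with most UMIs if a marker of it was among the 10 leading genes by fold and at least 3 of its markers were detected. The blood lists were merged into 1 leukocyte class. Leading genes were ranked by fold with a pseudocount of 10 CPM among genes with at least 10 UMIs and found in at least 10% of the cluster's barcodes. Shares have exact binomial (Clopper-Pearson) 95% intervals and were compared between libraries by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment (scipy 1.17.1, statsmodels 0.14.6).

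There were 15 function lists with 297 genes: chondrogenic, osteogenic, tendon, BMP and TGF-beta signalling, extracellular matrix and its processing, mechanosensing (these 6 are the HO-related lists), hypoxia and glycolysis, inflammatory cytokines and their receptors, neutrophil extracellular trap and oxidative burst, interferon response, antigen presentation, proliferation, immediate early and heat shock, platelet granule and thrombus, and osteoclast. Ahsp, Ctgf and Mx1 had no matching symbol, and Aldoa was left out because 2 gene IDs carry its symbol. Levels are counts per 1e6 UMIs (CPM) of the class sum per library, as mean ± SD of 2 libraries. A floor is 3 UMIs over the group's total, and folds against a group with 0 UMIs are bounds against it, the lower of those from the pooled level and from the mean of the libraries. Levels per 1e6 UMIs move with the haemoglobin share, which made up most erythroid-like UMIs.

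UMIs were summed per class and library for the 3 classes with at least 10 barcodes in each library and tested with edgeR 4.0.16 in R 4.3.3: genes passing filterByExpr, trimmed-mean (TMM) scaling, and the quasi-likelihood test with the library as a block, each class against the mean of the others. This left 2 residual degrees of freedom. The edgeR p-values lay close to those of a normal distribution, so the spread was almost wholly the one shared across genes. P-values were adjusted by Benjamini-Hochberg over the function-list genes tested and over all genes tested, with a threshold of 0.05. TMM factors ran from 0.0507 in erythroid-like sums to 4.93 in leukocyte sums, so directions were checked also with size factors of the DESeq2 kind and with total UMIs alone. Lists with at least 3 tested genes were compared with all other genes by camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated correlation. Barcodes with at least 2 of 28 mesenchymal markers were counted beside 1000 shuffles of each marker within library and 10 depth strata, and their sums were tested against all other kept barcodes in the same way for the HO-related lists.

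Genes named in the text follow a rule fixed before the data were examined. Per class, they are list genes past the threshold with the same sign in both libraries, at most 12 by the largest positive and 8 by the largest negative fold change. For the mesenchymal question, they are at most 30 markers and HO-list genes with at least 5 UMIs, by UMIs. Other genes, such as Pdgfra, Ptprc, Sox9, Acan, Sp7, Pdpn, Cadm1, Bgn, Fosb, Cd74, S100a8, the keratins and the mesothelial genes, were chosen after their values were seen.

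The test was tried on simulated data (3433 genes, dispersion 0.1, the mesenchymal-marker cluster against the mean of the other classes). It called 44 of 50 genes raised 4-fold (88%), 50 of 50 raised 16-fold, 14 of 41 tested genes at 0.25 of their level (34.1%) and 32 of 40 at 0.0625 (80%), with 2 false calls among 3252 unchanged genes. All simulated classes shared the same expression profile, taken from the sums other than erythroid-like. The haemoglobin shift between the real classes was thus absent, and these rates do not carry over to the real fits. Alternatives covered the barcode filters, doublet removal, cluster resolution, scaling, the filter on low counts, DESeq2 1.42.0, the block, the marker minimum and leaving out each replicate. Platelet-like barcodes were too few for a test and were left out of it.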

Results

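Single-cell RNA was measured in blood of wild-type mice after burn/tenotomy, an injury that combines a skin burn with cutting of a tendon and is followed by heterotopic ossification (HO), the formation of bone in soft tissue. Whole blood was passed through the iChip, a microfluidic device that enriches rare nucleated cells, and the recovered cells were barcoded on the 10x Chromium platform. The series concerns circulating mesenchymal progenitor cells (cMPCs) that carry an HO expression signature. The 2 libraries, replicate 1 and replicate 2, form 1 group. Blood of uninjured mice was not analysed here, so every comparison is between cell classes or between the libraries. Nothing in the labels says that the replicates came from separate mice, so the spread between these 2 libraries may be technical. P-values of edgeR, DESeq2 and camera rest on sums of these 2 libraries, with a spread estimated across genes in part or, in the edgeR tests, almost wholly. A gene's own difference between the libraries thus hardly enters its edgeR p-value. Those of Fisher's exact tests and permutations rest on barcodes within the libraries. A low p-value therefore does not show that the libraries agree, and none measures a spread between animals.

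Most of the RNA came from red cells. Haemoglobin transcripts made up 73.5% of the unique molecular identifiers (UMIs) in replicate 1 and 75.1% in replicate 2, led by Hbb-bs (29.1% and 28.5%), Hba-a1 (20.6% and 21.4%), Hba-a2 (16.1% and 17.6%) and Hbb-bt (7.72% and 7.74%). Next by UMIs was Gm42418, a locus that overlaps ribosomal RNA sequence, with 5.79% and 6.31%. Replicate 1 held 1008 barcodes, 3967318 UMIs, and a median of 2219 UMIs and 107 detected genes per barcode. Replicate 2 held 849 barcodes, 3329292 UMIs, and a median of 1643 UMIs and 97 genes. In 440 barcodes of replicate 1 (43.7%) and 328 of replicate 2 (38.6%), more than 20% of the UMIs were mitochondrial, with a median mitochondrial share of 94.7% and 94.8% among them. With at least 100 detected genes and at most 20% mitochondrial UMIs required, 471 barcodes of replicate 1 (46.7%) and 348 of replicate 2 (41.0%) were kept, 819 in all. Their median depth was 5628 and 5930 UMIs and 152 and 143 genes. Intervals and floors given below cover counting error only.

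**Figure D1:**
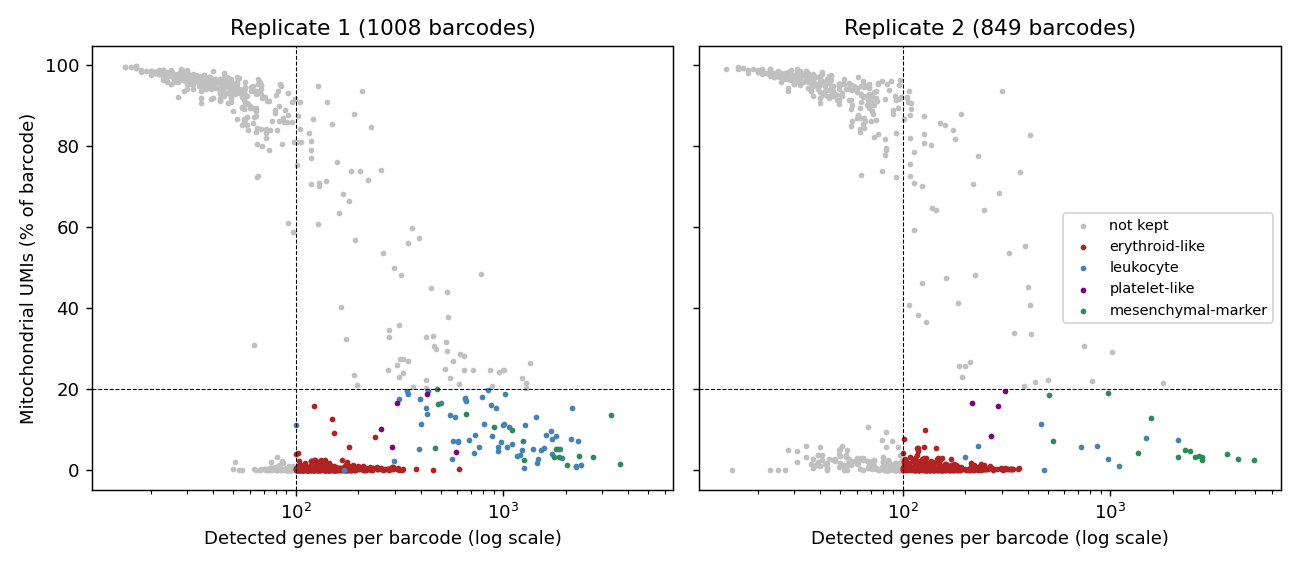
Each point is a barcode, placed by its number of detected genes (log scale) and its mitochondrial share of UMIs in percent, for replicate 1 (1008 barcodes) and replicate 2 (849 barcodes); dashed lines mark 100 genes and 20%. Barcodes of the mesenchymal-marker class lie at high gene numbers, with a median of 1761 and 2412 genes against 141 and 138 in the erythroid-like class.

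The first comparison asked which cells the enriched blood held and whether both libraries held them in like shares. Erythroid-like barcodes, named from haemoglobin and other red cell genes, were 384 of 471 in replicate 1 (81.5%, exact binomial 95% interval 77.7 to 84.9) and 319 of 348 in replicate 2 (91.7%, 88.3 to 94.3). A leukocyte cluster led by Arhgap15, Ebf1, Dock2, Ptprc and Bank1 held 65 barcodes in replicate 1 (13.8%, 10.8 to 17.2) and 10 in replicate 2 (2.87%, 1.39 to 5.22). A mesenchymal-marker cluster led by Mast4, Adamtsl1, Gpm6a, Igfbp5 and Rbfox1, with the fibrillar collagen gene Col3a1 among its 10 leading genes, held 17 barcodes (3.61%, 2.12 to 5.72) and 15 barcodes (4.31%, 2.43 to 7.01), a mean of 3.96% ± 0.496 (SD, n = 2). A platelet-like cluster led by Ppbp, Itgb3, Nrgn, Thbs1 and Tsc22d1 held 5 barcodes (1.06%) and 4 barcodes (1.15%).

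Leukocytes were 4.80 times as frequent in replicate 1 as in replicate 2 (two-sided Fisher's exact test, Benjamini-Hochberg adjusted over the 4 classes, adjusted p = 6.54e-08), and erythroid-like barcodes 0.889 times (adjusted p = 5.89e-05). The size of the leukocyte ratio depended on the setting: 7.02 with no barcode filter, 3.10 with at least 200 genes and 2.22 at Leiden resolution 0.3. The erythroid-like ratio was 0.610 with at least 200 genes and 0.878 with no mitochondrial filter. With no barcode filter it reversed to 1.07 and was no longer called (Fisher's exact test, adjusted p = 0.411). The mesenchymal-marker share did not differ detectably between the libraries (Fisher's exact test, adjusted p = 0.954). These tests compare 2 libraries and no conditions, and their p-values cover the counting of barcodes alone, not how libraries vary. By the marker list with most UMIs, at least 5 per barcode, the leukocyte cluster of replicate 1 held 29 B cell, 13 monocyte or macrophage, 5 neutrophil, 3 T cell and 1 dendritic cell barcodes and 14 with no such list, and that of replicate 2 held 5 B cell barcodes and 5 with no such list, a difference that was not tested. In replicate 2, 3 of the 10 barcodes of the leukocyte cluster carried at least 3 endothelial markers, and of these 3 barcodes 0 had a UMI of Ptprc, the pan-leukocyte phosphatase CD45. Scrublet marked 266 of 471 barcodes of replicate 1 (56.5%) and 1 of 348 in replicate 2 (0.287%) as doublets. In replicate 1 these were all 17 mesenchymal-marker, 64 of 65 leukocyte, 182 of 384 erythroid-like and 3 of 5 platelet-like barcodes. In replicate 2, 0 of 15 mesenchymal-marker and 0 of 10 leukocyte barcodes were marked. Scrublet's calls were not used, and with them removed and the rest clustered anew the ratio of erythroid-like shares turned to 1.22 (Fisher's exact test, adjusted p = 2.67e-07).

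**Figure D2:**
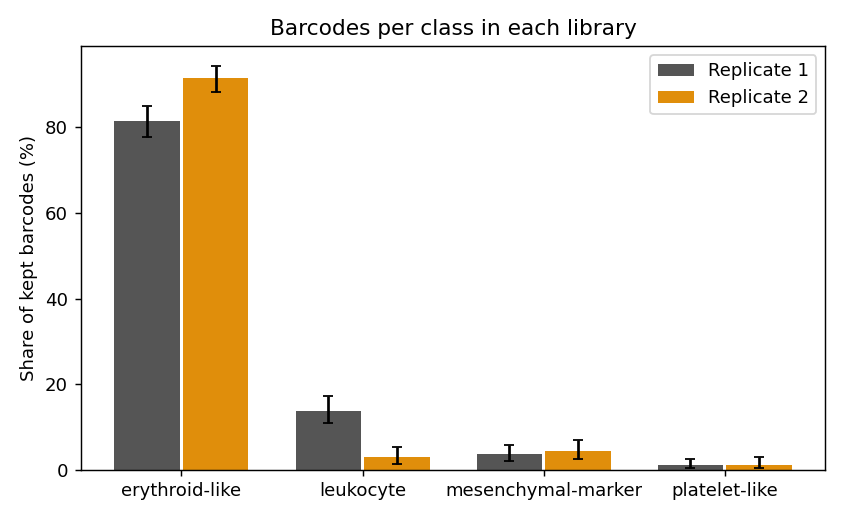
Bars give the share of kept barcodes in percent for each class in replicate 1 and replicate 2, with exact binomial 95% intervals. The leukocyte share differs between the libraries (13.8% and 2.87%), while the intervals of the mesenchymal-marker share overlap (3.61% and 4.31%).

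The next comparison asked which function genes set the erythroid-like class apart. Rsad2, an antiviral enzyme induced by interferon, was at 366 ± 30.2 UMIs per 1e6 UMIs of the class (CPM; SD, n = 2) in erythroid-like barcodes, against 5.85 ± 8.28 in the leukocyte cluster and 0 in the mesenchymal-marker cluster, at least 21.4-fold above the floor of 3 UMIs over the latter. Isg15, a ubiquitin-like interferon-induced protein, was at 157 ± 19.0 against 46.8 ± 66.2 and 25.4 ± 22.2. Bnip3l, which clears mitochondria from maturing red cells, was at 902 ± 74.5 against 35.1 ± 49.7 and 37.1 ± 25.0, and Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, at 125 ± 10.9 against 2.93 ± 4.14 and 0. The immediate early genes Jun, Fos, Junb, Atf3 and Klf4 and the NF-kappa-B genes Nfkbia and Nfkbiz had 0 UMIs in the 703 erythroid-like barcodes, a floor of 0.567 CPM, whereas Jun was at 675 ± 60.3 and Nfkbia at 716 ± 361 in the leukocyte cluster.

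In edgeR's quasi-likelihood test of class sums against the mean of the other classes, with Benjamini-Hochberg adjustment over the list alone, 7 of 97 function-list genes were higher and 41 lower in erythroid-like barcodes (7 and 42 when adjusted over all 3026 genes tested). The median log2 fold change of all genes was -3.85 in this class, 1.52 in the leukocyte and 2.12 in the mesenchymal-marker cluster, and 36 of the 41 lower genes lay below it. Rsad2 rose by a log2 fold change of 12.57 (SE 0.90, adjusted p = 2.69e-42 by edgeR) and Bnip3l by 10.59 (SE 0.75, adjusted p = 2.50e-42 by edgeR), each in both libraries. These fitted changes include the trimmed-mean factors, which were 0.0507 and 0.0692 in erythroid-like sums against 3.72 to 4.93 in the others. They are thus much larger than the CPM ratios above and are no measure of those ratios. Of the immediate early and heat shock list 12 of 17 genes were lower, of BMP and TGF-beta signalling 9 of 15, of inflammatory cytokines and their receptors 3 of 5, of extracellular matrix and its processing 3 of 8, and of mechanosensing and platelet granule genes 2 of 7 each. The interferon response list moved both ways, with 2 genes higher and 3 lower of 10, as did hypoxia and glycolysis, with 2 higher and 3 lower of 6. Jund and Gapdh were higher under the trimmed-mean scaling (log2 fold changes of 3.16 and 2.01) but lower when scaled by total UMIs alone (-2.95 and -4.04). Sox6, of the chondrogenic list, was counted among the higher genes (2.19, SE 0.82, edgeR adjusted p = 0.0182), but replicate 1 and replicate 2 differed in sign and its level was 6.37 ± 6.64 CPM, with 32 of 36 UMIs in replicate 1. DESeq2 called 6 genes higher and 4 lower: Jun, Rap1b, Nfkbia and Nfkbiz.

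The leukocyte cluster carried antigen presentation, oxidative burst and cytokine genes. The class II genes H2-Eb1, H2-Ab1 and H2-Aa, which present peptides to T cells, were at 277 ± 43.6, 268 ± 56.0 and 265 ± 60.1 CPM (SD, n = 2), and their transactivator Ciita at 156 ± 3.05. All of these had 0 UMIs in the other 2 tested classes, so that H2-Eb1 was at least 14.8-fold above the floor of the mesenchymal-marker cluster. Tnf, an inflammatory cytokine, was at 339 ± 117 and at least 19.8-fold above that floor, Srgn, a granule proteoglycan, at 1203 ± 37.7 and at least 69.2-fold, and Cybb, the catalytic subunit of the phagocyte oxidase, at 315 ± 83.7 and at least 18.5-fold. S100a8 and S100a9, neutrophil calcium-binding proteins, were found in replicate 1 (1940 and 2379 UMIs in 6 and 5 barcodes) and had 0 UMIs in the leukocyte cluster of replicate 2.

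By edgeR's quasi-likelihood test, 40 of 97 function-list genes were higher and 6 lower in this cluster (adjusted over the list alone, and the same counts over all genes). Of inflammatory cytokines and their receptors 5 of 5 genes rose, of the neutrophil extracellular trap and oxidative burst list 4 of 4, of antigen presentation 6 of 8, of platelet granule and thrombus 5 of 7 and of immediate early and heat shock 11 of 17, all above the median of all genes. The filter on low counts left 5 of 28 cytokine, 4 of 15 trap and 8 of 14 antigen presentation genes to test. A gene found almost only in leukocytes could pass it only by being high there, so these counts do not test a list. The only osteoclast gene tested, Nfatc1, rose by 4.50 (SE 1.38, edgeR adjusted p = 0.00342). Tnf rose by 7.47 (SE 1.37, edgeR adjusted p = 8.09e-07) and Srgn by 6.02 (SE 0.86, edgeR adjusted p = 2.35e-10). Isg15, Oasl2 and Jund were lower (-3.31, -2.39 and -2.28) but turned to 0.0611, 0.73 and 0.95 when scaled by total UMIs alone, which called 75 genes higher and 2 lower, a share of higher calls of 97.4% against 87.0%. DESeq2 called 7 higher (Srgn, Runx1, Cd74, Rap1b, Nfkbiz, Jun and Nfkbia) and 6 lower, and Tnf and the class II genes did not pass.

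The central question of the series is whether blood cells with mesenchymal genes carry skeletal-lineage genes. The 28 mesenchymal markers gave 257 UMIs in the cluster in replicate 1 and 630 in replicate 2, a level of 4831 ± 1854 CPM (SD, n = 2), against 235 ± 175 in the leukocyte cluster and 1.01 ± 0.937 in erythroid-like barcodes. A marker UMI was present in 15 of 17 barcodes (88.2%) and 15 of 15 (100%) of the cluster, in 10.8% and 40% of leukocyte barcodes, and in 0.260% and 1.25% of erythroid-like barcodes. Median depths were 4045 and 6102 UMIs in the cluster, 1779 and 1755.5 in leukocytes, and 6885.5 and 6216 in erythroid-like barcodes. Col3a1 was at 1634 ± 1012, Dcn, a small collagen-binding proteoglycan, at 1254 ± 87.9, Col1a2 at 460 ± 108 and Col1a1 at 204 ± 153. Pdgfra, a receptor of many mesenchymal progenitors, had 1 UMI in the cluster, and Ptprc was found in 0 of its 32 barcodes. Genes of other cell types were high in the same barcodes: the epithelial or keratinocyte list was at 1506 ± 696 CPM against 128 ± 181 in leukocytes, and 12 mesothelial genes, chosen after values were seen, gave 1216 UMIs, more than the 887 of the mesenchymal markers. The markers could enter the clustering, so these levels describe the cluster and test nothing.

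The function-list genes were left out of the clustering. Among them, Timp3, an inhibitor of matrix metalloproteinases (ENSMUSG00000020044, mm10 chromosome 10, 86300372 to 86349506), was at 569 ± 47.0 CPM in the cluster and had 0 UMIs in leukocytes, at least 35.8-fold. Ddr2, a collagen receptor kinase (ENSMUSG00000026674, chromosome 1, 169972307 to 170110762), was at 267 ± 8.99 and at least 16.9-fold. Bmpr1b and Bmpr1a, type I BMP receptors (ENSMUSG00000052430, chromosome 3, 141837136 to 142169425, and ENSMUSG00000021796, chromosome 14, 34410734 to 34503341), were at 421 ± 149 with 0 leukocyte UMIs, at least 26.7-fold, and at 319 ± 44.8 against 2.93 ± 4.14. Sox5 and Sox6, partner transcription factors of Sox9 in cartilage (ENSMUSG00000041540, chromosome 6, 143828425 to 144781977, and ENSMUSG00000051910, chromosome 7, 115470872 to 116038796), were at 829 ± 125 against 127 ± 35.1 and at 1297 ± 110 against 2.93 ± 4.14 in leukocytes, with Sox6 at 6.37 ± 6.64 in erythroid-like barcodes. Runx1 (ENSMUSG00000022952, chromosome 16, 92601466 to 92826149), which blood and cartilage precursors share, went the other way, with 1 UMI in the cluster and 144 in leukocytes. The coordinates are those of whole genes, and all 7 are annotated as protein-coding.

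As groups, the BMP and TGF-beta signalling list was at 3731 ± 142 CPM in the cluster against 1777 ± 22.4 in leukocytes, extracellular matrix and its processing at 2652 ± 923 against 439 ± 248, mechanosensing at 1759 ± 105 against 812 ± 156, and the osteogenic list at 915 ± 306 against 350 ± 59.9. The chondrogenic list was at 2186 ± 11.0 against 993 ± 27.6, but Sox5 and Sox6 made up 373 of its 384 UMIs in the cluster (97.1%), and Runx1 144 of its 192 UMIs in leukocytes (75%). The tendon list was at 361 ± 26.7 against 201 ± 77.7, immediate early and heat shock genes at 4278 ± 761 against 4670 ± 423, and hypoxia and glycolysis at 752 ± 1.92 against 1075 ± 217. Antigen presentation was at 972 ± 542 against 3067 ± 299, inflammatory cytokines at 683 ± 192 against 2792 ± 1703, platelet granule genes at 1012 ± 210 against 4097 ± 578, the trap and oxidative burst list at 85.9 ± 44.0 against 1081 ± 515, and osteoclast genes at 16.6 ± 4.10 against 162 ± 11.3. Interferon response genes were at 1223 ± 200 against 1865 ± 1550 and proliferation genes at 242 ± 168 against 605 ± 86.1.

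Many genes of the chondrogenic and osteogenic lists were not detected. In all 1857 barcodes, 13 of 26 chondrogenic genes had 0 UMIs, among them Col2a1, Col10a1 and Ihh, and 14 of 23 osteogenic genes, among them Sp7, Bglap, Ibsp and Spp1, which allows up to 0.411 CPM. The tendon regulators Scx and Mkx were among 6 tendon genes with 0 UMIs, and Nog, Grem1, Chrd and Gdf5 were the 4 of the BMP list. Sox9 had 1 UMI, in the cluster, and Acan had 1, in a barcode over the mitochondrial limit. Runx2, the master regulator of bone formation, had 2 UMIs in the cluster and 45 in leukocytes, all of these in 7 barcodes of replicate 1. In the cluster alone the floor was 17.1 CPM, so lower levels were not detectable at this depth.

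**Figure D3:**
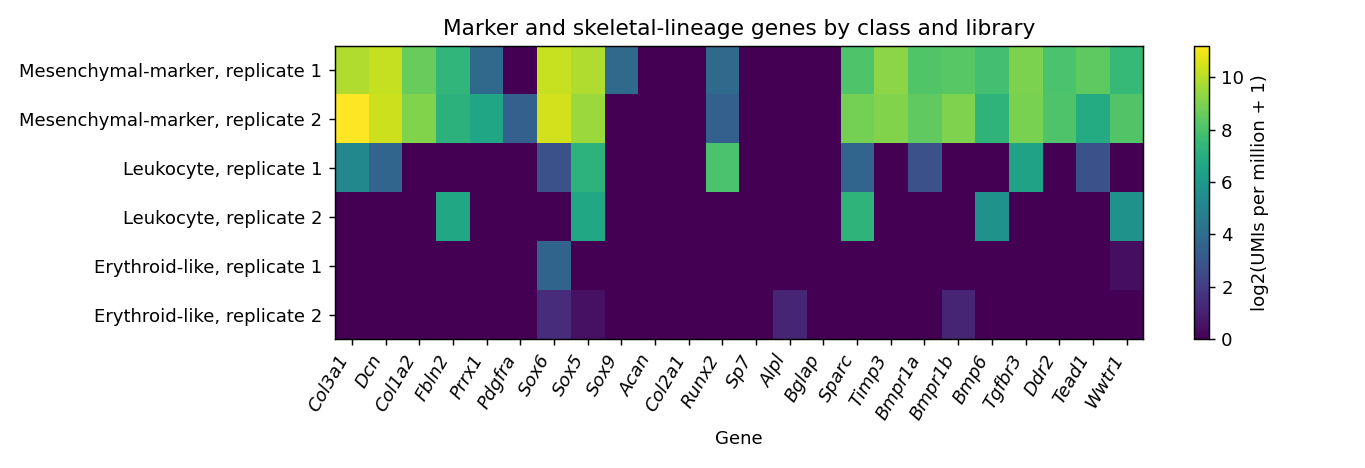
Colour gives log2 of CPM plus 1 for mesenchymal markers and skeletal-lineage genes (columns) in the mesenchymal-marker, leukocyte and erythroid-like classes of each library (lines). Sox6, Sox5, Timp3, Bmpr1a and Ddr2 are high in both libraries of the mesenchymal-marker class, where Col2a1, Sp7, Alpl and Bglap are at 0.

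Against the mean of the other classes, edgeR's quasi-likelihood test called 49 of 97 function-list genes higher and 7 lower in the mesenchymal-marker cluster (adjusted over the list alone; 46 and 6 over all genes), and 46 of the 49 lay above the median of all genes. Of the extracellular matrix list 8 of 8 genes rose, of BMP and TGF-beta signalling 14 of 15 (12 above the median), of mechanosensing 6 of 7, and of the osteogenic list 2 of 3 (Sparc and Tnfrsf11b). These are changes of the cluster as a whole, which also carried the epithelial and mesothelial genes above. The filter on low counts left 8 of 27 matrix, 15 of 38 BMP and TGF-beta, 7 of 15 mechanosensing and 3 of 23 osteogenic genes to test. A gene found almost only in this cluster could pass that filter only by being high in it. The counts per list therefore describe the cluster and do not test a list, here or against leukocytes alone. Sox5 and Sox6 rose and Runx1 fell, the 3 chondrogenic genes tested, and the tendon list had Egr1 alone, which rose by 4.02 (SE 1.17, edgeR adjusted p = 0.00222). Timp3 rose by 8.51 (SE 1.14, edgeR adjusted p = 1.02e-11), 6.39 above the median, Bmpr1a by 6.62 (SE 1.17, 1.60e-07 by edgeR), Sox6 by 5.11 (SE 0.79, 4.99e-09 by edgeR), and Runx1 changed by -4.76 (SE 1.20, 3.04e-04 by edgeR). Of the other lists 10 of 17 immediate early genes rose, interferon response had 2 genes higher and 2 lower of 10, and Ube2c, Rsad2, Isg15, Srgn, Cybb and Bnip3l were the lower genes besides Runx1. Fitted fold changes of genes with 0 UMIs in another class depend on the prior count and are no bounds. DESeq2 called 4 genes higher (Sox6, Sox5, Fosb and Bmpr1b) and 7 lower, and Timp3, Ddr2 and Bmpr1a did not pass.

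Because that mean gives the erythroid-like class the same weight as leukocytes, the cluster was also set against leukocytes alone, a contrast chosen after seeing the data. There, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the list alone gave 20 genes higher and 17 lower, with a median of all genes of 0.14. Of the extracellular matrix list 5 of 8 genes were higher, of BMP and TGF-beta signalling 5 higher and Tgfb1 lower of 15, of mechanosensing 3 of 7, and of the osteogenic list 2 of 3, while antigen presentation had 5 of 8 lower, the trap and oxidative burst list 4 of 4 and inflammatory cytokines 2 of 5. Sox6 was higher by 8.28 (SE 1.21, edgeR adjusted p = 4.35e-10), Sox5 by 2.81 (SE 0.76, edgeR adjusted p = 0.00125) and Timp3 by 8.55 (SE 1.42, edgeR adjusted p = 5.30e-08). Of the immediate early and heat shock list Fosb alone was higher of 17 genes, and Egr1 did not pass (0.84, SE 0.79, edgeR adjusted p = 0.422). With DESeq2 this contrast left Sox6 and Bmpr1b higher and Srgn, Runx1 and Cd74 lower.

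No function list moved as a whole in any class when limma's camera set it against the other genes (0 of 12 lists past an adjusted p of 0.05 in each class). At an unadjusted p under 0.05, camera gave 4 lists in the mesenchymal-marker cluster, with BMP and TGF-beta signalling and extracellular matrix up and antigen presentation and trap genes down (lowest adjusted p = 0.0601 by camera), 3 in leukocytes (lowest adjusted p = 0.109) and the interferon response alone in erythroid-like barcodes (adjusted p = 0.185), a list whose median log2 fold change there was -0.08 but lay above that of all genes. With an estimated correlation the lowest adjusted p was 0.676, 0.588 and 0.782. Without the filter on low counts, camera called 6, 4 and 4 of 15 lists.

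A further comparison asked whether mesenchymal genes fell together in single barcodes, independently of the clusters. At least 2 of the 28 markers were found in 16 barcodes of replicate 1 (3.40%, 1.95 to 5.46) and 16 of replicate 2 (4.60%, 2.65 to 7.36). Of these 32 barcodes 29 were in the mesenchymal-marker cluster, 3 in the leukocyte cluster and 0 in erythroid-like clusters, and 0 had a Ptprc UMI. Shuffling each marker between barcodes of the same library and depth decile gave a median of 27 barcodes and a maximum of 39 (permutation p = 0.13, one-sided, 1000 permutations). This count is a weak test of whether markers fall together, because shuffling spreads them over more barcodes: at least 1 marker was found in 46 barcodes against a shuffled median of 175 (permutation p = 1), and among barcodes with at least 200 genes 32 with at least 2 markers stood against 53 (permutation p = 1). With at least 3 markers, 27 barcodes stood against a median of 4 and a maximum of 12 (permutation p = 0.001, the smallest that 1000 permutations give). After thinning to 500 UMIs, 17 barcodes with at least 2 markers stood against a median of 3 (permutation p = 0.001). The shuffle matched barcodes by depth and not by cell class, and most kept barcodes were erythroid-like. Low p-values could thus arise for any genes that erythroid-like barcodes lack. They do not show that mesenchymal markers in particular belong together. Other settings of the minimum of 2 went both ways. Without Ly6a, Thy1, Serping1, Fstl1 and Cxcl12, which other cells make too, 30 barcodes stood against 21 (permutation p = 0.007), without barcodes with Ptprc 32 against 25 (permutation p = 0.044), with no barcode filter 80 against 54 (permutation p = 0.001), and with no mitochondrial filter 62 against 61 (permutation p = 0.46). Replicate 1 alone gave 16 against 10 (permutation p = 0.014) and replicate 2 alone 16 against 17 (permutation p = 0.73). A minimum number of markers sets this class, so it is a range of marker numbers, and whether its barcodes form a type was not tested. Near the minimum, 5 of its barcodes had exactly 2 markers, and 14 other barcodes had 1. Median depth was 4695 UMIs and 1847.5 genes in these barcodes and 5911 UMIs and 145 genes in the others.

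**Figure D4:**
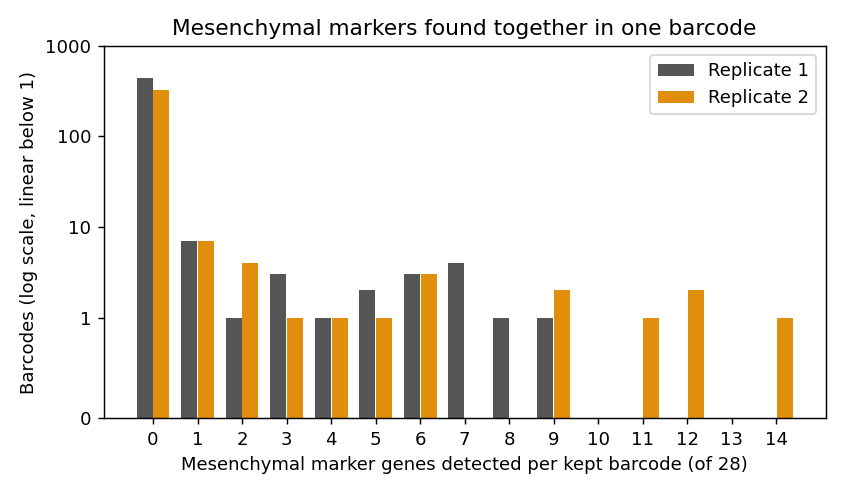
Bars give the number of kept barcodes (log scale, linear below 1) by how many of the 28 mesenchymal markers they carried, in replicate 1 and replicate 2. Most barcodes had 0 markers (448 and 325), 7 in each library had 1, and the rest reached up to 14.

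These 32 barcodes were then set against all other kept barcodes for the HO-related genes. By edgeR's quasi-likelihood test, adjusted over the list alone, 25 of 57 HO-list genes were higher and 2 lower (24 and 2 over all 4580 genes tested), and the rest did not pass. The median of all genes was 0.22, and no list was tested as a whole. Genes found almost only in these barcodes could pass the filter on low counts only by being high in them. Of extracellular matrix and its processing 8 of 12 genes rose, of mechanosensing 4 of 11, of BMP and TGF-beta signalling 6 of 23, of the osteogenic list 4 of 6 (Sparc, Pdpn, Tnfrsf11b and Cadm1) and of the tendon list Bgn, while Sox5 and Sox6 rose and Runx1 fell. Ddr2 rose by 7.89 (SE 1.51, edgeR adjusted p = 4.90e-06), Timp3 by 6.97 (SE 1.24, edgeR adjusted p = 1.06e-06), Bmpr1a by 4.98 (SE 1.07, edgeR adjusted p = 3.90e-05) and Sox6 by 3.26 (SE 0.86, edgeR adjusted p = 6.51e-04), and Runx1 changed by -6.15 (SE 1.19, edgeR adjusted p = 4.90e-06), each in both libraries. Serpinh1, a collagen chaperone, rose by 3.64 (SE 1.18, edgeR adjusted p = 0.00543), but 62 of its 63 UMIs in the cluster were in replicate 2. Tgfb1 was lower (-3.71) but turned to 0.46 when scaled by total UMIs alone. DESeq2 called 15 genes higher and 1 lower. The fit rests on 1 residual degree of freedom, and as 29 of the 32 barcodes were in the mesenchymal-marker cluster, it is no second line of evidence.

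Agreement between the libraries was closest for red cells, which also had by far the most UMIs. Across genes with at least 10 UMIs, Pearson's r of log2(CPM + 1) between replicate 1 and replicate 2 was 0.97 in erythroid-like sums (994 genes), 0.36 in leukocytes (3428 genes), 0.48 in the mesenchymal-marker cluster (3481 genes) and 0.45 in platelet-like barcodes (108 genes). The sums of replicate 1 and replicate 2 held 2892061 and 2394588 UMIs in erythroid-like barcodes and 170891 and 19520 in leukocytes. They held 73006 and 102579 in the mesenchymal-marker cluster and 6251 and 3161 in platelet-like barcodes. Counting noise lowers r where UMIs are few, so the lower values alone do not show that these classes differ between the libraries. Genes are not independent replicates, and no test was made.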

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

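Of the tests in this part, the comparison of marker UMIs per barcode with erythroid-like barcodes was chosen only after the result was seen. Barcodes with more than 20% mitochondrial UMIs were in no class above and entered only the counts over all barcodes and the settings without a mitochondrial filter, yet some carried cell type markers beyond the limit that a count of 0 allows. At least 2 mesenchymal markers were found in 29 of 440 such barcodes in replicate 1 (6.59%, where 0 would allow up to 0.682%) and in 19 of 328 in replicate 2 (5.79%, limit 0.915%). At least 2 of the 12 mesothelial genes, chosen after their values were seen, were found in 21 and 16 of these barcodes. At least 2 platelet markers were found in 28 barcodes of replicate 1 (6.36%) and 29 of replicate 2 (8.84%). Among erythroid-like barcodes, 0 in either library had 2 mesenchymal markers, and 1 and 2 had 2 platelet markers. The median depth over the limit was 787.5 and 793 UMIs, well below that of erythroid-like barcodes.

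The mesenchymal markers gave 346 UMIs in these 768 barcodes, 201 in replicate 1 and 145 in replicate 2. Free RNA spread over all droplets is argued against, since marker UMIs per barcode were 63.3 times those of the deeper erythroid-like barcodes (95% interval 26.9 to 196; 5 UMIs in 703 barcodes). Damaged cells of separate types are a candidate explanation, of which only the separate types passed a test able to fail. In it, 70.9% of marker pairs within a barcode (1093 of 1542) came from the same list, against a median of 34.0% and a maximum of 37.9% after shuffling (permutation p = 0.001, the smallest that 1000 permutations give). Intact cells of separate types would pass it as well, so it says nothing on damage. Damage before or after blood collection was not tested, and with 1 group no biological explanation was tested.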

How the results depend on the processing

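The scaling by total UMIs alone, the contrast with leukocytes alone (with edgeR and with DESeq2), the gate fit without a mitochondrial filter and the fit without haemoglobin, mitochondrial and ribosomal-RNA-like genes were chosen after seeing the data; the other alternatives were set before the data were examined. Over all alternatives, 103 summary results stayed within their limits, 52 moved and 2 reversed. For named genes, edgeR and DESeq2 fits kept direction and threshold in 134 gene-by-setting results of the erythroid-like class (11 weaker, 4 reversed), 140 of leukocytes (16 and 6), 168 of the mesenchymal-marker cluster (23 and 0) and 296 of the barcodes with several markers (23 and 1). Scaling with size factors of the DESeq2 kind and dropping the replicate block changed none of these calls. Leiden resolution 1.0 gave every class the same barcodes as the main result. Its 51 results, counted above as kept, were therefore the same by construction.

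With no filter on genes or mitochondrial share, erythroid-like barcodes were 44.1%, and their ratio between libraries reversed to 1.07 and was no longer called (Fisher's exact test, adjusted p = 0.411). The mesenchymal-marker and platelet-like classes were not found (0%): their 32 and 9 barcodes fell in clusters whose median mitochondrial share was over 20%, so no class fit of them was possible. Barcodes with at least 2 markers then numbered 80, marker UMIs 478 and 789 (277 and 641 in kept barcodes), and 6 genes were lower in the fit of those barcodes. With at least 200 detected genes the shares were 53.4% erythroid-like, 31.0% leukocyte, 15.7% mesenchymal-marker and 0% platelet-like, as fewer barcodes were kept and the 9 platelet-like ones joined the leukocyte cluster, and 1 gene was lower in the barcodes with several markers. With no mitochondrial filter they were 74.4% erythroid-like, 6.05% mesenchymal-marker and 0% platelet-like, 62 barcodes had at least 2 markers, and 5 genes were lower in these. The leukocyte class, with 6 barcodes left in replicate 2, dropped out of that class fit, so the 72 genes lower in the erythroid-like class are from a contrast with the mesenchymal-marker class alone. Removing Scrublet calls reversed the erythroid-like ratio to 1.22 and left no separate leukocyte or platelet-like cluster (0% each). The cluster then named from mesenchymal markers (14.7%; 13 barcodes of replicate 1 and 80 of replicate 2) was a mixed class: it held 61 barcodes erythroid-like in the main result, 11 leukocyte, 6 platelet-like and 15 mesenchymal-marker ones, of which 0 were from replicate 1. Its fit, against the erythroid-like class alone, gave 19 genes higher and 3 lower (3 and 19 seen from the erythroid-like class) and reversed Jund and Gapdh to -0.075 and -1.19, so these counts are not of the same classes or contrast. Leiden resolution 0.3 merged the mesenchymal-marker and platelet-like clusters (0% each) into the leukocyte cluster. By that construction 91 genes were lower in erythroid-like barcodes and 91 higher in the merged cluster, where Sox6 (1.69), Bmpr1b (3.82) and Oasl2 (1.55) reversed. Apart from these constructions, the cause was not tested.

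Scaling by total UMIs alone gave 4 genes higher and 77 lower in the erythroid-like class, 75 and 2 in leukocytes, 4 lower in the mesenchymal-marker cluster, and 50 higher and 0 lower in the barcodes with several markers (edgeR, 50 at an unadjusted p under 0.05). It reversed Jund (-2.95) and Gapdh (-4.04) in the erythroid-like class, Isg15 (0.0611), Oasl2 (0.73) and Jund (0.95) in leukocytes and Tgfb1 (0.46) in the barcodes with several markers. This setting differed from the main fits only in leaving out the trimmed-mean factors, so the reversals come from the scaling. Those factors were 0.0507 and 0.0692 in erythroid-like sums and 3.72 to 4.93 in the other class sums. They were 5.12 and 5.34 in the barcodes with several markers, against 0.376 and 0.0973 in all others. DESeq2 called 4 genes lower in the erythroid-like class, 7 higher in leukocytes, 4 higher in the mesenchymal-marker cluster, and 15 higher and 1 lower in the barcodes with several markers. It weakened 38 of 78 named calls, and the cause was not tested. Against leukocytes alone 20 genes were higher and 17 lower in the mesenchymal-marker cluster, and 2 and 3 with DESeq2. Without the filter on low counts, 12 genes were higher in the erythroid-like class, and camera called 4 lists there, 4 in leukocytes and 6 in the mesenchymal-marker cluster, with more genes tested.

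The number of barcodes with at least 2 markers fell to 17 after thinning and was 16 to 16 with either replicate left out. The class and gate fits without a replicate have no residual degrees of freedom, so no test was possible. Without the replicate block, no count of calls moved by more than 1.5 times, with 53 genes higher and 9 lower in the mesenchymal-marker cluster. Depth limits the mesenchymal-marker cluster to levels above 17.1 CPM and leukocytes to 15.8.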

Other observations

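Of the tests in this part, those on barcodes without mesothelial genes and on thinned barcodes were chosen only after the result was seen, and the contrast with leukocytes alone was added after seeing the data. The mesenchymal-marker cluster also carried epithelial keratins. Krt19, a simple-epithelium keratin, was at 802 ± 107 CPM (SD, n = 2; 143 UMIs in 23 barcodes) with 0 UMIs in leukocytes and erythroid-like barcodes, at least 50.9-fold above the leukocyte floor. Krt14, a keratin of basal keratinocytes, was at 256 ± 245 (50 UMIs in 6 barcodes, 44 of them in replicate 2) with 0 UMIs in the same classes, while the keratinocyte genes Krt5 and Krt1 had 0 UMIs in all barcodes. Krt8 was at 316 ± 311 and Krt18 at 103 ± 48.1, and the epithelial or keratinocyte list as a whole at 1506 ± 696 against 128 ± 181 in leukocytes. The haematopoietic progenitor list was at 1339 ± 392 against 98.8 ± 67.2, but 163 of its 227 UMIs were Meis1, a homeobox gene used outside blood as well (970 ± 352).

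Other cell type lists lay on both sides of their level in leukocytes, and none of these differences was tested. B cell markers were at 6.85 ± 9.69 CPM against 8755 ± 3485 in the leukocyte cluster, neutrophil markers at 11.7 ± 2.79 against 14290 ± 20209, monocyte or macrophage markers at 433 ± 380 against 851 ± 1131, and T cell markers at 0 against 339 ± 480. Dendritic cell markers were at 187 ± 12 against 220 ± 94.1, plasma cell markers at 85.9 ± 44.0 against 49.0 ± 3.12, and eosinophil markers at 4.87 ± 6.89 against 69.5 ± 25.8. Endothelial markers were at 179 ± 18.4 against 459 ± 583, pericyte or smooth muscle markers at 159 ± 147 against 11.7 ± 16.6, Schwann cell markers at 217 ± 93.4 against 149 ± 78.7, and platelet or megakaryocyte markers at 129 ± 66.0 against 77.6 ± 35.2. NK cell markers were at 0 against 2.93 ± 4.14, skeletal muscle markers at 4.87 ± 6.89 against 2.93 ± 4.14, and basophil or mast cell markers at 0 in both. Erythroid genes were at 730 ± 343 in the cluster, against 12353 ± 15731 in leukocytes and 887589 ± 1358 in erythroid-like barcodes.

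Keratins beside collagens raised the hypothesis that the cluster holds mesothelial cells, which line the body cavities and express both. A list of 12 mesothelial genes written after some had been seen gave 1216 UMIs in the cluster (440 in replicate 1 and 776 in replicate 2) and 23 in leukocytes, led by Gpm6a (337 UMIs, also a leading gene of the cluster), Muc16 (202), Wt1 (150), Upk3b (145) and Upk1b (103). At least 3 of the 12 were present in 28 of 32 cluster barcodes (14 in each library), in 2 of 75 leukocyte barcodes and in 0 of 703 erythroid-like barcodes. Of the 12 genes, 9 had a UMI in leukocytes and 2 in erythroid-like barcodes, and 0 were in another list.

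Mesothelial cells may be the source: 6 further genes not looked at beforehand were 104 times as high in the cluster as in leukocytes (95% interval 18.2 to 4154; 96 UMIs against 1), although Ildr2 and Dmkn gave 90 of the 96, Calb2 had 1 and Itln1 had 0. Like the mesenchymal markers, these 6 genes could enter the clustering, so the ratio is not independent of how the cluster was made. For free RNA, barcodes were thinned to 500 UMIs. A UMI of the 12 genes was then 593 times as frequent in cluster barcodes as in erythroid-like ones (interval 97.8 to 24285). The shares were 84.4% against 0.142%, and 100% against 0.427% before thinning. As the 12 genes were picked from this cluster, that test cannot decide. Of the 6 further genes, with 96 UMIs in the cluster, 0 had a UMI in erythroid-like barcodes. For these genes, mostly Ildr2 and Dmkn, this argues against free RNA spread evenly over droplets, with the limit that they could enter the clustering that set the classes. Every barcode of the cluster carried a UMI of the 12 genes (100%), so none lacked all of them. Of its 29 barcodes with at least 2 mesenchymal markers, 0% (upper limit 11.9%) had at most 1 of the 12 genes. But those genes were picked from this cluster and could enter the clustering, so the test does not exclude connective tissue progenitors without mesothelial identity. Such progenitors stay open for part of the cluster. Whether the cells of this cluster were in the circulation or were carried over when the blood was taken stays open, because how it was drawn and whether the iChip would remove them are not given in the sources used here. Progenitors that share mesothelial genes and epithelial cells of other kinds also stay open, and with 1 group no biological explanation was tested.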
